A study of Mus musculus with 4 samples.

How the data were processed

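RNA from sorted bone marrow erythroblasts of mice lacking Parp2 and of wild type mice was measured on 4 Affymetrix whole-transcript arrays, 2 per genotype. Per the labels, the cells were sorted for the surface proteins Ter119 and CD71, the strain background was C57BL/6, and 100 ng of total RNA per sample was labelled. The authors deposited 1 table of log2 expression values with 35511 probe sets and 4 columns, and each column was assigned to its sample by its name. Per the submitters' processing notes, RMA, limma and R 3.0.2 were used; RMA gives background-corrected, quantile-normalised and summarised log2 values. Which role each tool had is not given in the sources used here, and the deposited log2 values were used without further normalisation. RMA compresses differences of dim and of very bright probe sets, so that folds there tend to be understated.

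Gene symbols came from the platform annotation, which gave 1 symbol to 21789 probe sets, several to 1621 and none to 12101. Of the probe sets with 1 symbol, 21698 had a gene ID found in a RefSeq gene table of the assembly GRCm38.p6, and 0 symbols had to be updated. That table served only for names and for the order of neighbouring genes, and coordinates are not used here. A probe set listed to several genes was tested and counted, and no gene was named from it. For gene lists each gene was represented by the probe set with the highest mean over the 4 arrays among those naming it alone, which gave 19938 genes. Of 999 genes with several such probe sets, 323 had probe sets with differences of both signs.

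Parp2 knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 arrays against 2, no further term) over the 23410 annotated probe sets. Calls required a Benjamini-Hochberg adjusted p under 0.05. The fit had 2 residual degrees of freedom and 4.77 prior degrees of freedom, with a prior SD of 0.416 on the log2 scale. A two-sided exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used for single genes. Nothing in the labels says that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical. The titles also open with numbers whose meaning is not given in the sources used here, 1 and 2 for wild type and 3 and 4 for the knockout; if they mark an order of processing, that order and the genotype cannot be told apart in any comparison. The number of arrays limits the precision of every value.

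Before the data were examined, 27 gene lists were fixed: p53 targets, replication stress and fork protection, base excision and single-strand break repair, the PARP family and ADP-ribose turnover, DNA replication, G2/M and mitosis, heme synthesis and iron handling, globins, red cell membrane and cytoskeleton, erythroid transcription factors, early erythroid and progenitor genes, late erythroblast and enucleation genes, EPO and STAT5 response, apoptosis regulators, interferon response, ATF4 and integrated stress response, hypoxia response, handling and immediate early genes, cytosolic ribosomal proteins, markers of 6 other groups of blood cells, sex-linked genes and the genes around Parp2. Some genes stand in more than 1 list, among them Bcl2l1, Bbc3, Sesn2, Btg2, Slc4a1, Cpa3 and Gata2. The 25 lists with at least 5 measured members, sex-linked genes excepted, were tested with camera at a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists. Camera asks whether a list differs more than other genes do. Also run were camera with an estimated correlation, and fry, which asks whether a list's genes move on balance in a single direction.

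The genes named are Parp2 and, in each direction, the 12 with the largest change past the test, filled with those of lowest unadjusted p among single-gene probe sets with an absolute log2 difference of at least 0.58 and non-overlapping groups. Then come the 2 to 4 members of each list with the lowest p, and members a list's description needs. Predicted genes need not be named. These rules, the tests and the alternatives were fixed before the data were examined. The alternatives were the replicate number as a block, leaving out each array, centring arrays on their medians, repeated quantile normalisation, a filter on dim probe sets, trended and robust moderation, array weights, all rows of the table, other thresholds, and the mean over a gene's probe sets.

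The tests were run first on simulated arrays with the real means and the fitted spread. In 10 simulations of 23410 probe sets, each with 200 changed, limma called 0.2% of probe sets changed by 1 on the log2 scale, 2.6% of those changed by 2, 43.8% of those changed by 3 and 82.2% of those changed by 4. It also called 33 of 232100 unchanged ones. In 50 simulations of independent genes with the p53 list shifted by 0.6, camera called that list in 100% with the preset correlation, and called 0.08% of the other lists. With an estimated correlation it called the shifted list in 0%. Random lists in the closing section were drawn 10000 times from 50 classes of mean expression, and permutation tests used 100000 resamples.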

Results

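Gene expression was compared between Parp2 knockout and wild type mouse erythroblasts, nucleated red cell precursors sorted from bone marrow by the erythroid protein Ter119 and the transferrin receptor CD71. Parp2 encodes a DNA-damage-dependent poly(ADP-ribose) polymerase. There were 2 arrays of each genotype, with normalised log2 values. Array medians over the annotated probe sets were 5.24 and 5.34 in wild type replicates 1 and 2, and 5.23 and 5.49 in knockout replicates 1 and 2. Knockout replicate 2 had the narrowest interquartile range, 1.98 against 2.62 to 2.94 on the other arrays.

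The targeted gene was examined first. Parp2 (probe set 10414497) read 8.24 and 7.65 on the wild type arrays and 7.11 and 6.70 on the knockout arrays. The difference was -1.04 ± 0.40 (SE, n = 2 per group) on the log2 scale, a 2.05-fold lower level. Both knockout arrays lay below both wild type arrays, the direction the labels call for. The limma p for this probe set alone was 0.0368 without adjustment. The difference was not past the limma test over all probe sets (adjusted p = 0.9999). Which part of the transcript was deleted and which part the probe set covers were not analysed here.

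The next comparison asked which genes differed between the genotypes. The gene with the lowest p was Phlda3, a p53-induced inhibitor of Akt signalling, with a difference of +3.24 ± 0.37 (SE, 2 arrays per group), or 9.46-fold. Others with higher values in the knockout were Ccnb1ip1 (+3.07), a meiotic recombination factor, the p53 target genes Eda2r (+2.63), Zmat3 (+2.15) and Dglucy (+2.14), the mitochondrial carrier Slc25a36 (+2.55), the heat shock gene Hspa1a (+2.35), the noncoding RNA Pvt1 (+1.95), Exoc4 (+1.82), the zinc finger gene Zfp958 (+1.52), the transcription factor Jun (+1.44) and the corepressor Cbfa2t3 (+1.35). Probe set 10443463, listed to several genes, had a difference of +3.91 ± 0.45. Lower values were found for the pre-B cell receptor component Vpreb1 (-2.90), the B cell surface protein Ms4a1 (-2.00), the tetraspanin Cd9 (-2.22), the protease Ctsc (-2.15), the myeloid lectin receptor Clec12a (-2.10) and Chil3 (-1.96), a chitinase-like protein of myeloid cells. The small nucleolar RNAs Snora20 (-2.72) and Snord53 (-1.82), and Tmem229b (-2.61), Gpr137b-ps (-2.16), Lypla2 (-1.94) and Rgs18 (-1.70), were also lower. Genes were chosen for non-overlapping groups, and none of them passed the adjusted test; the lowest adjusted p was 0.744, for Phlda3.

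Limma called 0 of 23410 probe sets at an adjusted p under 0.05. With the arrays split by the replicate number in their titles it called 724. Part of the spread within each genotype thus followed that number, and the 0 is no evidence that the genotypes were alike. By genotype 486 had an unadjusted p under 0.05, of which 80 were higher and 406 lower in the knockout, where chance alone would give about 1170. With the replicate number as a block, which leaves 1 residual degree of freedom, there were 1432, so the count below chance depends on the model. Groups did not overlap for 5853 probe sets, or 25% of them, with 3647 higher and 2206 lower, and chance gives 16.7% per direction. The count of calls was 5 without wild type replicate 1 and 62 without wild type replicate 2. The share of higher values among the unadjusted calls was 16.5%, but 26.9% after repeated quantile normalisation and 52.4% without knockout replicate 2.

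**Figure D1:**
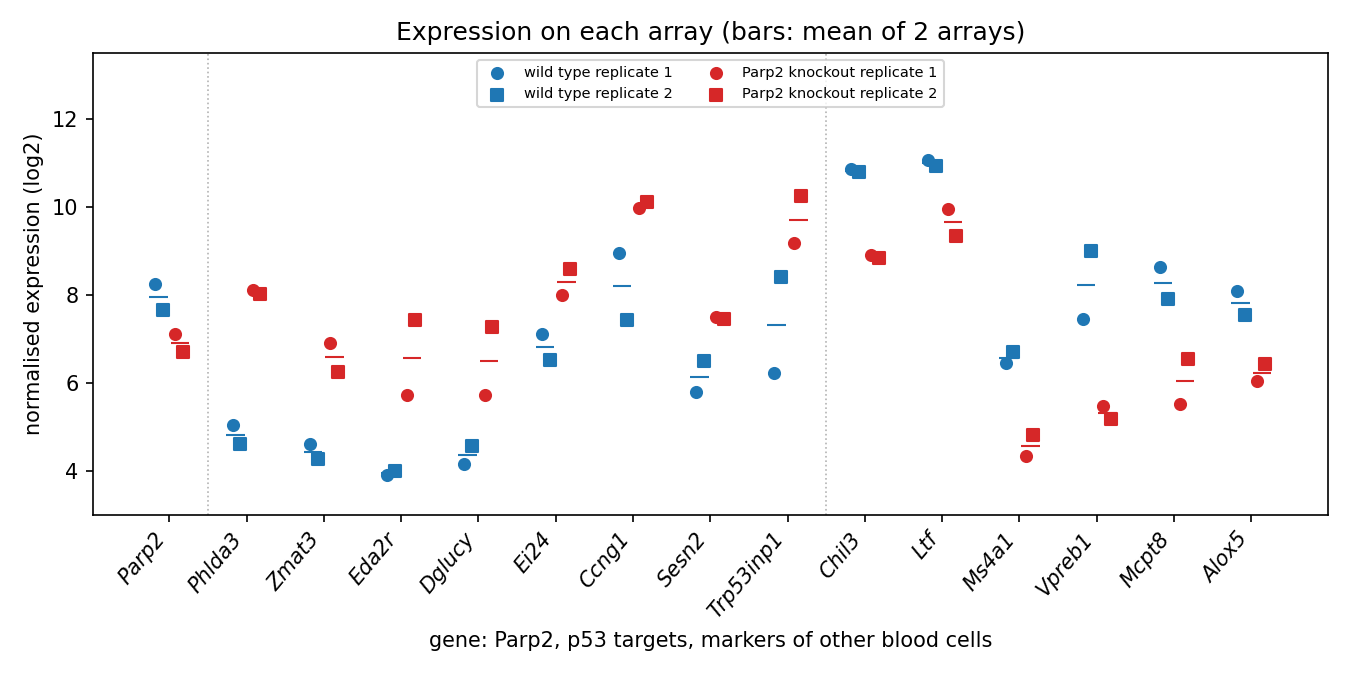
Normalised expression (log2, vertical axis) of Parp2, 8 p53 target genes and 6 marker genes of other blood cells on each of the 4 arrays. The p53 targets are the 8 of lowest p, and the 6 markers were picked among those lower in the knockout. Members that hardly differed or went the other way are not drawn. Circles and squares are replicates 1 and 2, blue is wild type, red is Parp2 knockout, and bars are means of 2 arrays. Phlda3 read 8.10 and 8.02 on the knockout arrays against 5.04 and 4.60 on the wild type arrays.

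Gene lists were then compared as groups. Targets of the tumour suppressor p53 rose in the knockout (camera, adjusted p = 5.68e-12). With an estimated correlation the adjusted p = 0.5145, and with fry it was 0.501. Of 32 listed targets 29 were measured. Cdkn1a, Bax and Gdf15 had no probe set naming them alone and were not tested. Of the 29 measured targets 24 were higher, 19 of them on both knockout arrays above both wild type arrays, and the median difference was +0.57. Adjusted over the list alone, 3 members passed (Phlda3, Zmat3 and Eda2r), and 0 passed over all probe sets; the 3 became 1 when arrays were centred on their medians, 5 without wild type replicate 2, 5 without knockout replicate 1 and 7 with trended and robust moderation. Further members with their values were Trp53inp1 (+2.39), cyclin G1 gene Ccng1 (+1.85), Polk (+1.71), a translesion DNA polymerase, Ei24 (+1.48), Sesn2 (+1.33), the pro-apoptotic gene Bbc3 (+1.01) and Mdm2 (+0.82), which encodes the ubiquitin ligase that degrades p53. Ddb2 (-0.58), Rrm2b (-0.65) and Fas (-0.32) had lower values, and Pmaip1 (+0.02) and Xpc (+0.00) hardly differed. The other-cell markers described next moved with the genotype at the same time.

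Neutrophil markers fell in the knockout (adjusted p = 5.35e-23, and adjusted p = 0.5145 with an estimated correlation). All 18 were lower, 15 of them without overlap, with a median difference of -1.47. With 1 array left out the median ranged from -2.00 (without wild type replicate 2) to -0.77 (without wild type replicate 1). Chil3 passed adjusted over the list alone, and Ltf (-1.35), Ly6g (-1.74) and Itgam (-1.57) came next; without wild type replicate 1 or without knockout replicate 2, 0 members passed, 10 did without wild type replicate 2 and 4 without knockout replicate 1. The count was 0 among the brighter probe sets, and 2 after repeated quantile normalisation or with trended and robust moderation. The abundant S100a8 and S100a9 differed by -0.40 and -0.43, at levels between 12.6 and 13.3. B cell markers fell as well (adjusted p = 1.64e-12, and adjusted p = 0.3969 with an estimated correlation): 11 of 13 were lower, with a median of -1.03, and Ms4a1, Vpreb1 and Igll1 (-1.40) passed adjusted over the list alone, where 1 did without wild type replicate 2 or without knockout replicate 2. Markers of mast cells, basophils and eosinophils fell (adjusted p = 1.92e-08, and adjusted p = 0.5145 with an estimated correlation), with 11 of 12 lower and a median of -0.70. That median was -0.35 without wild type replicate 1 and -1.25 without wild type replicate 2. Mcpt8 (-2.24), a basophil protease, and Alox5 (-1.58) passed adjusted over the list alone. Of these markers 0 passed without wild type replicate 1, knockout replicate 1 or knockout replicate 2, and after repeated quantile normalisation, 1 passed among the brighter probe sets or with trended and robust moderation, and 5 passed without wild type replicate 2.

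Monocyte and macrophage markers fell (adjusted p = 9.56e-06, and adjusted p = 0.5145 with an estimated correlation). Of 16 measured, 12 were lower, and the median was -0.69, with Adgre1 (-1.12), Lyz2 (-0.97) and Cd68 (-1.02) as examples. The call ended without wild type replicate 2 (median -0.50) and without knockout replicate 1 (median -0.18). T and NK cell markers fell (adjusted p = 0.0176, and adjusted p = 0.7877 with an estimated correlation), with 9 of 12 lower and a median of -0.28, Nkg7 (-1.63) and Cd3g (-0.92) being the members of lowest p. That call ended without wild type replicate 2, where the median was +0.04, without knockout replicate 1 (median -0.12) and among the brighter probe sets (median -0.17). Megakaryocyte and platelet markers did not pass (adjusted p = 0.338): 7 of 10 were higher, with a median of +0.33, among them Pf4 (+1.14), while Gp9 was at -0.62. This list passed as higher without wild type replicate 2 (median +0.53), and its median was -0.07 without wild type replicate 1 and -0.04 without knockout replicate 2.

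Early erythroid and progenitor genes fell (adjusted p = 0.011, and adjusted p = 0.608 with an estimated correlation), with 12 of 16 lower and a median of -0.39. Ccnd2 (-1.07), the stem cell factor receptor gene Kit (-1.26), Cdk6 (-1.45) and the transcription factor Myb (-0.80) had the lowest p. Markers of mast cells, which share Cpa3 and Gata2 with this list, and of other blood cells fell at the same time. The call ended without wild type replicate 1 (median -0.20) and without knockout replicate 2 (median -0.19). It also ended after repeated quantile normalisation (median -0.31, camera adjusted p = 0.0692) and among the brighter probe sets (median -0.45, camera adjusted p = 0.161). Without wild type replicate 2 the median was -0.65.

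**Figure D2:**
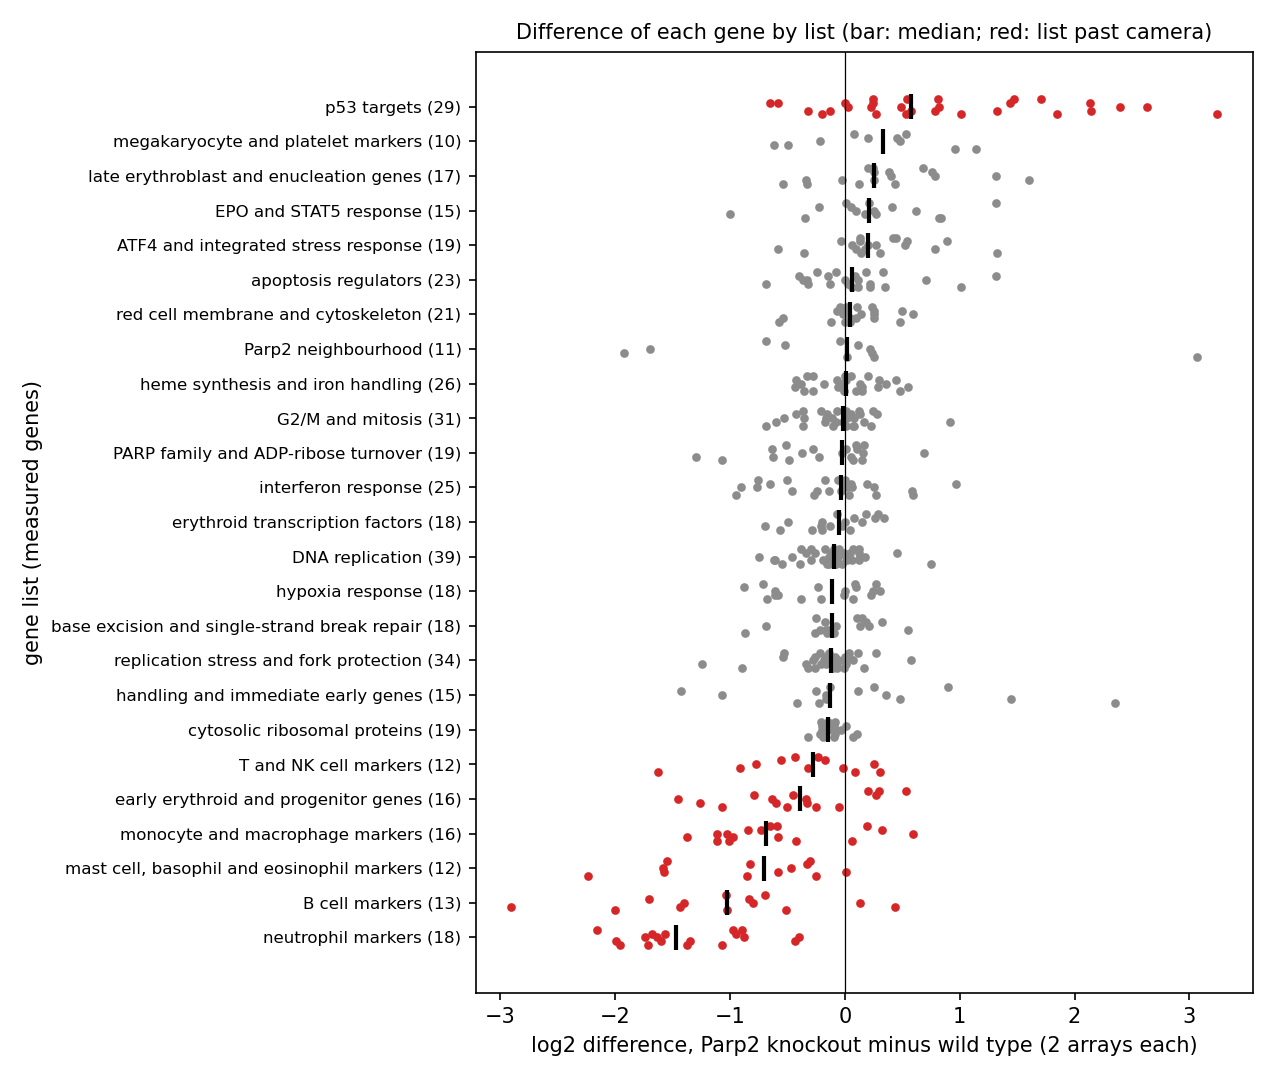
Log2 difference of each measured gene, knockout minus wild type (horizontal axis, 2 arrays per group), in 25 gene lists (vertical axis, with the number of measured genes). Black bars are list medians, and red marks the 7 lists past the camera test with the preset correlation, which lie between a median of -1.47 for neutrophil markers and +0.57 for p53 targets.

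Lists of mature red cell genes did not pass the test. The red cell membrane and cytoskeleton list had a median of +0.05 over 21 genes (adjusted p = 0.998), with Icam4 at -0.57 and Tspo2 at -0.54. Heme synthesis and iron handling had a median of +0.01 over 26 genes (adjusted p = 0.705), although camera's direction was lower, with Uros at +0.48 and the iron exporter Slc40a1 at -0.44. Erythroid transcription factors had a median of -0.05 (adjusted p = 0.338), with Runx1 at -0.57 and Ldb1 at -0.70. Late erythroblast and enucleation genes had a median of +0.25 (adjusted p = 0.338), with Xpo7 at +1.60 and Bcl2l1 at +1.31. Among the brighter probe sets the median was +0.32 and passed the test. Without wild type replicate 1 the medians were -0.49 for this list, -0.50 for the red cell membrane list and -0.30 for the heme list. Without wild type replicate 2 they were +1.01, +0.47 and +0.44. Leaving out 1 array leaves the replicate numbers unbalanced between the genotypes. Every median given with 1 array left out, here and for other lists, thus carries part of the difference by number. That difference (number 2 minus number 1) was +1.03 for the late erythroblast, +0.76 for the red cell membrane and +0.48 for the heme list. EPO and STAT5 response genes had a median of +0.21 (adjusted p = 0.247), with Erfe, the erythroid hormone that suppresses hepcidin, at +0.82 and Stat5b at -1.0. Of the 10 genes in the fixed globin list, only 3 had a probe set naming them alone, too few to test. The embryonic genes Hbb-y and Hba-x differed by -0.93 and -0.49.

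Lists of genome maintenance and the cell cycle did not pass either. Replication stress and fork protection genes had a median of -0.12 over 34 genes (adjusted p = 0.0839), with Smarcal1 at -0.90 and Rad1 at -1.24; the list passed as lower without wild type replicate 1 (median -0.19) and without knockout replicate 1 (median -0.51) and as higher without knockout replicate 2 (median +0.29). DNA replication genes had a median of -0.09 (adjusted p = 0.181), with Gins4 at +0.75 and Gmnn at -0.61, and G2/M genes one of -0.02 (adjusted p = 0.202), with Kif2c at -0.68 and Ttk at -0.60. DNA replication genes passed at a median of -0.42 without knockout replicate 1 and of +0.31 without knockout replicate 2, and G2/M genes at -0.43 without wild type replicate 1 and +0.28 without wild type replicate 2. Base excision and single-strand break repair genes had a median of -0.11 (adjusted p = 0.435), with Ogg1 at -0.87 and Neil2 at +0.55. The other members of the PARP family and ADP-ribose turnover had a median of -0.02 (adjusted p = 0.0895), with Parp6 at -1.07 and Parp8 at -1.29, and passed as lower without wild type replicate 1 (median -0.25) or without knockout replicate 1. Apoptosis regulators had a median of +0.06 (adjusted p = 0.790), with 14 of 23 genes higher. Among them Bbc3, shared with the p53 list, was at +1.01, Casp8 at -0.69 and Apaf1 at +0.71.

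Stress lists did not pass. ATF4 and integrated stress response genes had a median of +0.20 (adjusted p = 0.0895), with Sesn2, shared with the p53 list, and Ddit4 (+0.78) of lowest p, and passed as higher without wild type replicate 2 (median +0.24) and among the brighter probe sets (+0.25). Hypoxia response genes had a median of -0.11 (adjusted p = 0.0895), with Bnip3 at -0.68 and Pfkfb3 at -0.61, and interferon response genes one of -0.03 (adjusted p = 0.181), with Sting1 at -0.95 and Mx2 at +0.58. Interferon genes passed at -0.66 without wild type replicate 1 and at +0.34 without wild type replicate 2. Handling and immediate early genes went both ways, with a median of -0.13 and a mean of +0.14 (adjusted p = 0.790); Hspa1a and Jun were higher, and Klf6 (-1.07) and Zfp36 (-1.43) lower. Cytosolic ribosomal proteins had a median of -0.14 (adjusted p = 0.166), with Rpl8 at -0.32 and Rps14 at -0.21, and passed as lower without knockout replicate 1 (median -0.41). Sex-linked genes were read per array: Xist lay between 3.92 and 4.09 and Eif2s3y between 6.70 and 8.45 on the 4 arrays.

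The genes on either side of Parp2 were compared last. The list of neighbours did not shift as a whole (camera, adjusted p = 0.32), with a median of +0.02 and a mean of -0.09 over 11 genes, while fry's mixed-direction p was 0.0109 without adjustment. Adjusted over the list alone 3 of the 11 passed, namely Ccnb1ip1 (+3.07 ± 0.56), Rpph1 (-1.92 ± 0.42), the RNA component of RNase P, and Pnp (-1.69 ± 0.38), purine nucleoside phosphorylase; 1 passed without wild type replicate 2 or after repeated quantile normalisation. In reference order Rpph1 is the measured gene next to Parp2. Apex1, a base excision repair endonuclease nearby, differed by -0.69 ± 0.71, and Osgep by -0.04 ± 0.37.

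**Figure D3:**
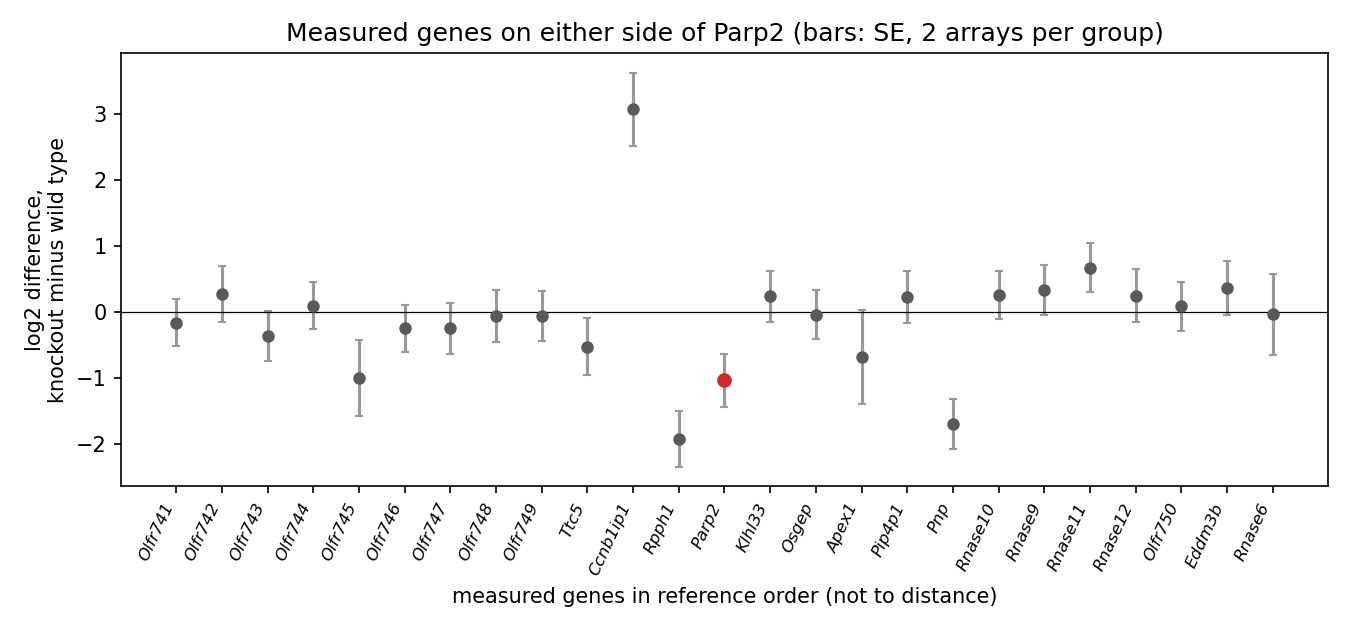
Log2 difference, knockout minus wild type (vertical axis), of the 25 measured genes nearest to Parp2 in reference order (horizontal axis, not drawn to distance). Points are differences of means with SE bars (2 arrays per group), and red marks Parp2 at -1.04; Ccnb1ip1 stands at +3.07, Rpph1 at -1.92 and Pnp at -1.69.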

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

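The count of probe sets past the test (0) was 5 to 62 with 1 wild type array left out and 0 with 1 knockout array left out, a range of 0 to 62. It was 8 with trended and robust moderation, and 486 at an unadjusted p under 0.05 with at least 1.5-fold change. Centring, repeated quantile normalisation, the filter on dim probe sets, array weights, all rows of the table and an adjusted p under 0.1 gave 0. The replicate numbers in the sample titles may or may not pair the arrays, since only 2 pairs share a number and no label says what it marks; the 2-minus-1 differences of the genotypes correlated at 0.468 across probe sets. With the number as a replicate block, 274 probe sets passed (50 higher, 224 lower), with 1 residual degree of freedom and 1 SD of 0.406 shared by all probe sets, so that calls followed the size of the difference (1.40 or more on the log2 scale); 10 of them differed in sign between the numbers. The block also added the late erythroblast (adjusted p = 0.00511) and ATF4 lists (adjusted p = 0.0245) to those past camera, and adjusted over the list alone 11 p53, 16 neutrophil, 7 B cell and 4 mast cell list members passed. Parp2 kept its direction in all settings, from -1.33 to -0.74. The count of lists past the test (7) was 8 to 13 with 1 array left out, 9 with the block, 6 or 7 in the other settings with preset correlation, 0 with an estimated correlation and 0 with fry. In simulated data of independent genes, camera with an estimated correlation did not find the p53 list shifted by 0.6. Correlated genes, fry, other lists and other sizes were not simulated. On the 4 arrays the estimated correlation was 0.21 for the p53 list, 0.61 for neutrophil, 0.34 for mast cell and -0.01 for B cell markers, against the preset 0.01. The simulation therefore does not show which setting is right for these data. The p53, neutrophil, B cell and mast cell lists passed under every setting except the estimated correlation and fry. The cause of other changes was not tested.

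For lists that did not pass, camera's direction changed in the following settings, given with the list's median. After repeated quantile normalisation medians were 0.0638 for DNA replication, 0.15 for G2/M, 0.19 for heme synthesis and 0.12 for erythroid transcription factors. Among brighter probe sets they were -0.0163 for G2/M, 0.0079 for heme synthesis and -0.0466 for erythroid transcription factors. The heme list stood at 0.0079 with the block and with fry, and the red cell membrane list at -0.0274 after centring and 0.0456 with array weights. Medians alone also changed sign, with camera's direction kept: after repeated quantile normalisation for replication stress (0.0182), base excision repair (0.0207), interferon response (0.0642), handling genes (0.0518) and ribosomal proteins (0.0287), and after centring for heme synthesis (-0.0651), apoptosis regulators (-0.0136) and the Parp2 neighbourhood (-0.0579). With 1 array left out, medians ranged from -0.51 to 0.29 for replication stress, -0.11 to 0.0428 for base excision repair, -0.42 to 0.31 for DNA replication, -0.43 to 0.28 for G2/M, -0.30 to 0.44 for heme synthesis, -0.50 to 0.47 for the red cell membrane, -0.10 to 0.0559 for erythroid transcription factors, -0.49 to 1.01 for late erythroblast genes, 0.0304 to 0.15 for apoptosis regulators, -0.66 to 0.34 for interferon response, -0.20 to 0.37 for handling genes, -0.41 to 0.15 for ribosomal proteins, -0.0721 to 0.53 for megakaryocyte markers and -0.26 to 0.14 for the Parp2 neighbourhood. With 1 array left out, the lone array is assumed to vary like the other genotype.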

Other observations

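The tests in this part, apart from those by genotype on lists fixed beforehand, were chosen after the results they bear on had been seen. The arrays differed more by the replicate number in their titles than by genotype. With arrays numbered 2 set against those numbered 1, 724 probe sets passed limma's adjusted test, 220 higher and 504 lower in number 2, against 0 by genotype and 0 in the remaining split of the 4 arrays; a count this large points to a structure of the samples. Late erythroblast and enucleation genes were higher in number 2 (median +1.03, camera adjusted p = 2.55e-08), as were red cell membrane genes (+0.76), heme synthesis genes (+0.48) and interferon response genes (+0.56). DNA replication genes (-0.45), early erythroid and progenitor genes (-0.68), ribosomal proteins (-0.43) and neutrophil markers (-0.71) were lower. Other cells' markers went both ways, since those of monocytes and macrophages (+0.64), T and NK cells (+0.51) and megakaryocytes and platelets (+0.42) were higher. Single genes included the globin Hbq1a (+4.22), Mir144 (+3.33), an erythroid microRNA, the spermidine synthase gene Srm (-3.22) and the metallothionein Mt2 (-2.97). Camera with the preset correlation called 13 of 25 lists in this split and 10 in the remaining one, against 7 by genotype, so a call by itself is weak evidence here. The p53 list had a p of 6.82e-13 by genotype, 0.0289 by number and 0.288 in the remaining split.

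Small nucleolar RNAs, a list made after Snora20 and Snord53 had been seen, passed camera with the preset correlation but not with an estimated one. Without those 2 genes, 49 had a median difference of -0.42 by genotype (camera unadjusted p = 0.00289 with the preset correlation and p = 0.255 with an estimated correlation). With the preset correlation the same 49 differed as much by number (median -0.54, p = 0.000196) and also in the remaining split (+0.17, p = 0.00385). The knockout median was -0.10 in the pair numbered 1 and -0.61 in the pair numbered 2, so the genotype difference lies mostly in 1 pair. Of all 51, 10 were lower and 6 higher without overlap, where chance gives 16.7% per direction.

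The p53 targets were higher in the knockout. A difference confined to the arrays of 1 number would spare the other same-number pair. The median was +0.52 in number 1 and +0.59 in number 2, above all 10000 brightness-matched random lists in each (lower percentile 100). An equal effect of number in both genotypes would cancel within each pair. It would also cancel in the genotype difference, since each genotype had 1 array of each number, so by itself it cannot give this difference. The pair values make up the genotype difference already seen. Random lists hold genes drawn independently, while the targets had an estimated correlation of 0.21, so the percentiles are no separate evidence for the list. The narrow range of knockout replicate 2 does not account for the 0.52, which comes from the pair without that array. Fewer other cells in the knockout sorts would raise erythroid genes as much. Relative to genes of like brightness, 80 erythroid genes had medians of +0.21 in number 1 and +0.07 in number 2. For the p53 targets these medians were +0.49 and +0.76. The permutation test compared the means of these brightness-adjusted values, not the medians. Its permutation p = 0.078 in number 1 and p = 0.00001 in number 2 (the smallest that 100000 resamples can give). The first is not under 0.05, so this explanation stays open. The handling list did not pass by genotype, with members of both signs, and a p53 response to the loss of Parp2, a difference in cell source and an order of processing also stay open.

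Markers of other blood cells were lower in the knockout. The narrow range of knockout replicate 2 does not account for the neutrophil, B cell, mast cell and monocyte parts, whose medians in the pair without that array were -1.258, -0.647, -1.464 and -0.948, at percentiles 0, 0.12, 0 and 0 of random lists; in the pair numbered 2 the neutrophil and B cell medians (-1.27 and -1.03) lay at percentile 0, the mast cell and monocyte medians at 8.43 and 10.6, the progenitor median at 4.12 in number 1 and 37.55 in number 2, and the T and NK cell median at 4.96 and 0.01. Estimated correlations were 0.61 for neutrophil, -0.01 for B cell, 0.34 for mast cell and 0.14 for monocyte markers, while random lists hold genes drawn independently. Each pair is also 1 array against 1, so the percentiles are no separate evidence for these lists. An equal loss of all other cells would lower megakaryocyte and platelet markers alike. These 10 (median level 5.74) had means of +0.18 and +0.33 in the 2 pairs. The means were -0.80 and -0.63 for 48 markers of the other types within their range of levels (median level 6.17), with permutation p = 0.0093 and p = 0.0014, genes taken as independent. The 48 come from the other-cell lists called lower, and the 10 from the other-cell list that was not. That choice shaped these p-values, so they do not decide the question. The mean of the 10 over all arrays, +0.25, was -0.04 without wild type replicate 1 and -0.12 without knockout replicate 2, against -0.79 and -0.88 for the others. Fewer cells of some types in the knockout sorts and lower expression in the sorted cells both stay open, since no test here separates them. The sort for Ter119 and CD71 should remove neutrophils, yet the 18 neutrophil markers had a median level of 9.5, against 5.20 for all probe sets. S100a8 and S100a9, the most abundant markers, differed by -0.40 and -0.43 near the top of the scale (13.9), where differences tend to be understated.

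Genes beside Parp2 differed in the knockout. Bright genes here had a mean over the 4 arrays above 5.20, the median of all probe sets. Ccnb1ip1, at 3.80 in wild type and 6.87 in the knockout, passed this filter only through its knockout level. Of the 5 nearest bright genes on each side, Ccnb1ip1 was higher while Rpph1 and Pnp were lower, so the direction is mixed. Without these 3, which prompted the test, the other 7 had a mean absolute difference of 0.22, against a median of 0.21 over 10473 equal windows along the reference order with their 3 largest left out (percentile 57.07), so nothing beyond the 3 genes stood out. An effect of the altered allele on its neighbours, DNA that came with it from another strain and a sequence variant under the probes were not tested and stay open.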
